A study of Nothobranchius furzeri with 10 samples.

How the data were processed

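RNA of muscle was sequenced in 10 samples of male Nothobranchius furzeri, 5 exercised in a swim tunnel and 5 with no perturbation, from total RNA with the TruSeq RNA Library Preparation Kit v2, per the labels. Samples were grouped by the source and perturbation labels. The replicates were numbered within each group. The submitters' processing notes list bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads shared by several gene models were not given in the sources used here, so overlapping, antisense and near-identical gene models cannot be separated with certainty.

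The deposited count table holds whole-number read counts for 26739 gene models in 10 columns, with a different total in each, and was used as deposited. The deposited RPKM table holds values scaled by gene model length and library total by the authors; how they were computed was not given in the sources used here. Counts divided by RPKM gave 1 length per gene model only with the library totals running down the rows, so the deposited RPKM were used only as an alternative. Lengths were taken from the largest RPKM of each gene model under that reading (22169 gene models, median 2446 bases), and RPKM were recomputed from the counts, these lengths and each library's own total. All columns mapped to a sample by title.

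The identifiers matched 0 of the entries in the reference gene table used here (assembly NfurGRZ-RIMD1), and the tables do not pair them with names. The 44 gene lists fixed before the data were examined, the tests of those lists and the levels of tfam and egfp were therefore not analysed here. The rule for naming genes, also fixed before the data were examined, was to name tfam and egfp, then the gene models past the threshold with a symbol, at least 5 CPM and no overlap between groups, with the 10 largest changes each way, and up to 4 members of each list. Where fewer than 10 passed, the 10 with the lowest p-values were to be given by value as not passing. That last part applied; without names, identifiers were printed for only the 2 with the lowest p-values in each direction.

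Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM factors, group as the only term, gene models kept by filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjusted p under 0.05. This design, and the alternatives not described as added, were fixed before the data were examined. The standard error of a log2 fold change was approximated as its size over the square root of the F statistic. Normalised CPM used TMM-scaled totals, and log2 CPM a prior count of 2. Principal components were taken on log2 CPM of the tested gene models, and group differences in scores and in library measures were tested by exact permutation, two-sided. The deviation of a library was the log2 of CPM plus 0.5 less its median over libraries.

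Alternatives were RLE and upper-quartile factors, library totals only, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, limma on log2 of the deposited RPKM plus 0.1 or plus 1, 1 surrogate variable from sva 3.50.0, and each library left out in turn. Added after the data had been seen were the fit without the 2 libraries that stood apart (with the same alternatives), the recomputed RPKM and the second component. Fold changes from RPKM are on the log2(value + pseudocount) scale and understate changes of low gene models. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

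Each test was tested on simulated data made from the real means, totals and dispersions with 200 changed gene models. The changed ones were drawn from gene models with a mean count of at least 20, so recovery at lower counts was not measured. For the comparison of 10 libraries (15337 gene models), edgeR recovered 9% of 2-fold and 73% of 4-fold changes with 0 false calls, and DESeq2 30% and 95% with 52 false calls. Voom with quality weights recovered 8% and 76% with 1 false call, and edgeR with 1 surrogate variable 2% and 58% with 4 false calls. The simulated libraries carried no shift shared by 2 libraries. For the comparison of 8 libraries (15200 gene models), edgeR recovered 68% and 97% with 8 false calls, DESeq2 74% and 99% with 31, voom 63% and 96% with 6, and edgeR with 1 surrogate variable 52% and 97% with 9. Replicates were checked for duplicate libraries: over 20 pairs within groups, the lowest chi-square per degree of freedom was 27.6, far above sampling noise, so each library was counted once. Totals of 25927913 to 40433810 counts make counting error small for abundant gene models, and reads amplified by PCR without molecular identifiers are not independent molecules.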

Results

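Muscle transcriptomes were compared between male turquoise killifish (Nothobranchius furzeri, a short-lived annual fish) that had exercised in a swim tunnel and males with no such perturbation. All samples came from line 4010 at an age of 10 weeks. The strain label names a transgene of mylz2, a myosin light chain gene of fast muscle, with egfp, a green fluorescent protein, and tfam, a mitochondrial DNA-binding transcription factor. Each group held 5 samples, and the design asked which transcripts differed in muscle after physical exercise. The labels do not state that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. Read counts covered 26739 gene models. The gene models carry identifiers without names in the tables used here, so transcripts are given by identifier and the levels of tfam and egfp were not analysed here.

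Total counts were 33475011 ± 5621640 (SD, n = 5) per exercised library and 29626874 ± 2497033 (SD, n = 5) per unexercised library, and ranged from 25927913 to 40433810 over the 10 libraries. The groups did not differ in total counts beyond the spread between libraries (p = 0.238, exact permutation test, two-sided, and adjusted p = 0.873 over 4 library measures). Between 19458 and 20388 gene models had at least 1 count per library. The 10 most abundant gene models together took 38.5% ± 7.33 of the counts in exercised libraries and 38.2% ± 7.87 in unexercised libraries (SD, n = 5 each; p = 0.849, exact permutation test, adjusted p = 0.873). In each group 1 library had a far lower share, given below. Splits that put both in 1 group give larger differences, so this p does not test the groups. The single most abundant gene model took 12.4% ± 3.52 of the counts in exercised and 12.6% ± 3.62 in unexercised libraries (SD, n = 5 each).

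One library in each group stood apart. In exercised replicate 3 the 10 most abundant gene models took 25.8% of the counts, and in unexercised replicate 4 they took 24.2%, against 39.6% to 43.9% in the other 8 libraries. Both libraries had 16536 gene models with at least 10 counts, against 14740 to 15709 in the others. Among 13691 gene models with a mean above 1 CPM, the count scaled to the library total, 5884 lay above 2-fold of their median over the libraries in exercised replicate 3 and 5896 in unexercised replicate 4. The other libraries had 41 to 206 such gene models. These counts used library totals. With TMM-scaled totals, an alternative added after the data had been seen, they were 2458 and 2548, against 53 to 295 in the others. With the same scaling, 1587 and 1669 gene models lay more than 2-fold below the median, against 53 to 256 in the others. With library totals these lower sets were 321 and 384, against 43 to 471. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.977 between these 2 libraries and at 0.815 to 0.847 between either of them and the other 8.

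The first principal component of log2 CPM held 64.5% of the variance and followed these 2 libraries, at scores of 126.1 and 133, with the other 8 between -38.1 and -25.7. The exact permutation p of the group difference on it was 0.516 (252 splits, two-sided). With 1 of the 2 libraries in each group that p could not fall below 0.452, as 112 splits put both in 1 group and give a larger difference, so it does not test the groups. The second component held 10.6% of the variance. On it the exercised libraries scored 3.7 to 42.5 and the unexercised libraries -31.4 to -10.4, with no overlap. The exact permutation p of that difference was 0.00794, the smallest that 5 samples against 5 can give; the component was tested after the first one had been seen.

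**Figure D1:**
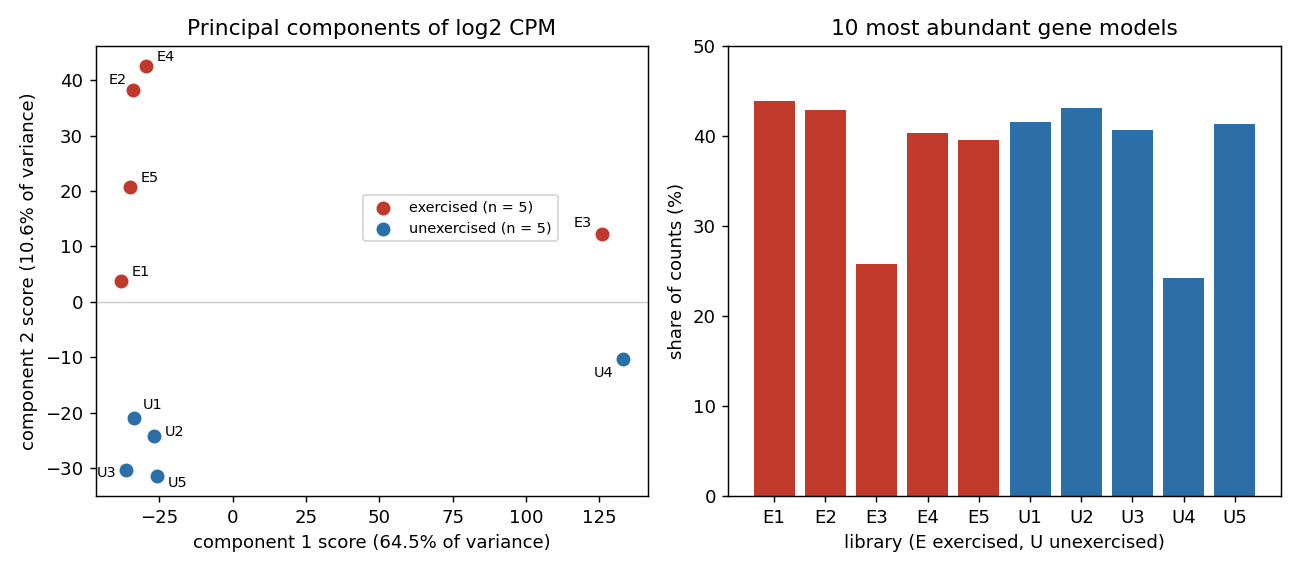
Left, scores of the 10 libraries on the first 2 principal components of log2 CPM, in red for exercised (E1 to E5) and blue for unexercised (U1 to U5) libraries. Right, the percentage of counts taken by the 10 most abundant gene models in each library; E3 and U4 stand at 25.8% and 24.2%, below the 39.6% to 43.9% of the others.

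With all 10 libraries, none of 15337 tested gene models passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The lowest adjusted p was 0.0753. At an unadjusted p under 0.05 there were 1461 gene models, 912 higher and 549 lower in exercised muscle, where independent gene models give 767 by chance. Of 100 splits of the 10 libraries, counted after the data had been seen, 39 gave as many, the real one included. Among the 62 splits that part the 2 libraries that stood apart, only the real one did. Every exercised library lay beyond every unexercised library for 418 gene models (2.73% against 0.79% by chance), 255 of them higher and 163 lower in exercised muscle. Other tests of the same 10 libraries did call gene models at the same threshold. DESeq2 called 391, limma voom with quality weights 1819, and edgeR with 1 surrogate variable 836. In simulated data of 10 libraries DESeq2 made 52 false calls, against 0 for edgeR, 1 for voom and 4 with 1 surrogate variable. There edgeR recovered 9% of 2-fold and 73% of 4-fold changes, so its 0 calls leave room for missed changes. The simulated libraries carried no shift shared by 2 libraries, so these numbers do not rank the tests on the real libraries. Voom gave exercised replicate 3 and unexercised replicate 4 weights of 0.122 and 0.116, against 0.745 to 2.33 for the others. Without exercised replicate 3 the edgeR test called 244 gene models and without unexercised replicate 4 it called 84.

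The 10 gene models with the lowest p-values held 7 with a higher and 3 with a lower mean in exercised muscle, by 1.78-fold to 5.91-fold. None passed the threshold in the edgeR test of all 10 libraries. Nfu_g_1_000946 had 74.7 ± 20.7 normalised CPM in exercised and 16.2 ± 5.68 in unexercised muscle (SD, n = 5 each), a log2 fold change of 2.21 ± 0.295 (SE; edgeR adjusted p = 0.0753). Its lowest exercised library had 43.0 CPM and its highest unexercised library 24.1 CPM. Nfu_g_1_004892 had 5.70 ± 1.17 CPM in exercised and 1.83 ± 0.506 CPM in unexercised muscle (SD, n = 5 each; log2 fold change 1.63 ± 0.233, SE; edgeR adjusted p = 0.0753). In the other direction, Nfu_g_1_007294 had 4.79 ± 0.47 CPM in exercised and 18.9 ± 6.38 CPM in unexercised muscle (SD, n = 5 each; log2 fold change -1.98 ± 0.267, SE; edgeR adjusted p = 0.0753). Nfu_g_1_019970 had 12.9 ± 3.88 CPM in exercised and 45.3 ± 13.5 CPM in unexercised muscle (SD, n = 5 each; log2 fold change -1.81 ± 0.264, SE; edgeR adjusted p = 0.0753). For each of the 4, all 5 exercised libraries lay on one side of all 5 unexercised libraries. With all 10 libraries, each of the 4 had an adjusted p under 0.05 in DESeq2, in limma voom with quality weights and in edgeR with 1 surrogate variable. Each also had one in edgeR without exercised replicate 3, without unexercised replicate 4 and without both. The 4 were chosen by their p-values in these same libraries. Their lack of overlap and their low adjusted p-values therefore follow in part from the choice and are no separate test.

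**Figure D2:**
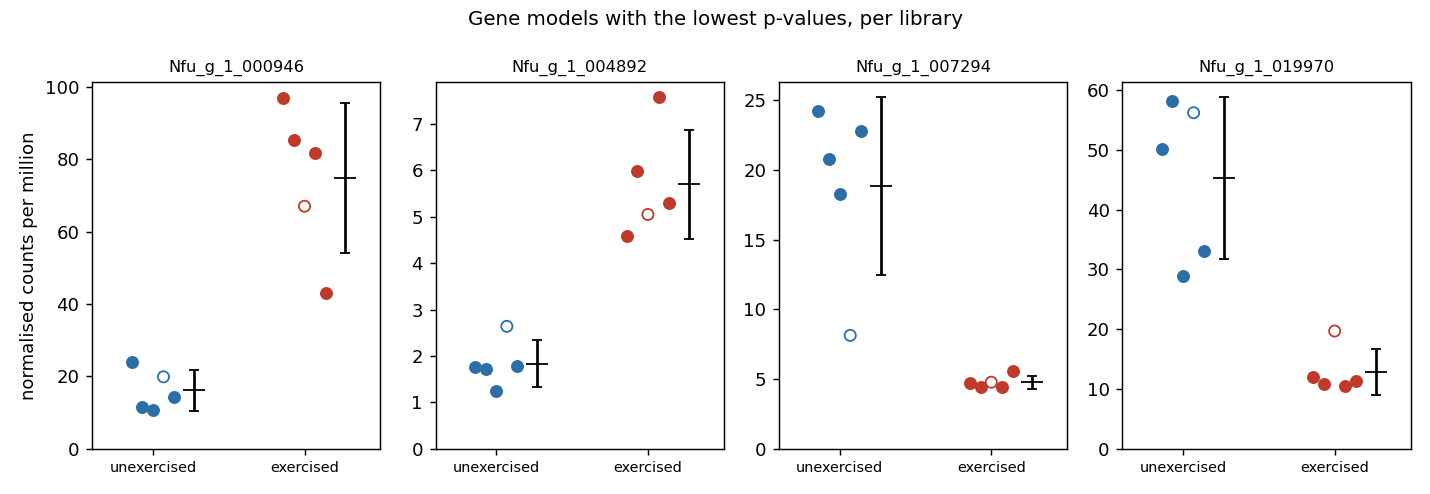
Normalised CPM of 4 gene models in each of the 10 libraries, blue for unexercised and red for exercised, with open circles for exercised replicate 3 and unexercised replicate 4. Black marks give the group mean and SD (n = 5 each). In each panel the groups do not overlap, and the gene models were chosen by their p-values in these libraries.

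The test was repeated after the data had been seen, without the 2 libraries that stood apart and with 4 libraries per group. It called 964 of 15200 gene models, 602 higher and 362 lower in exercised muscle, with 3280 at an unadjusted p under 0.05. Independent gene models give 760 by chance, and among all 35 splits of the 8 libraries into 4 and 4 the highest after the real one gave 2427. The groups of 4 separated on the first component, which held 31.8% of the variance (p = 0.0286, exact permutation test, the smallest that 4 against 4 can give). The called gene models differed by a median of 1.90-fold where higher (quartiles 1.64 and 2.32) and 1.82-fold where lower (quartiles 1.61 and 2.17). More than 2-fold differences were found for 264 of those higher and 121 of those lower. More than 4-fold differences were found for 27 and 6. The groups of 4 did not overlap for 561 of the 602 and 349 of the 362. Over all 15200 gene models, called or not, 13.16% had groups that did not overlap, where chance gives 2.86%. All 10 gene models with the lowest p-values above were among the 964, but the 8 libraries are part of the 10, so this is no separate test.

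For the 4 gene models given above, the log2 fold changes with 8 libraries were 2.33 ± 0.312 for Nfu_g_1_000946 and 1.84 ± 0.207 for Nfu_g_1_004892, and -2.17 ± 0.136 for Nfu_g_1_007294 and -1.93 ± 0.21 for Nfu_g_1_019970 (SE). Their edgeR adjusted p-values with 8 libraries were 0.00496, 0.00175, 0.00011 and 0.00165 in that order.

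The calls were counted in 4 groups of gene models by abundance, and the difference between these groups was not tested. Among the 3810 least abundant gene models (0.31 to 1.66 CPM), 32 gene models were called higher and 40 lower. In the next group (1.67 to 5.21 CPM) there were 138 higher and 108 lower, and in the one after it (5.24 to 16.2 CPM) 216 higher and 115 lower. Among the 3774 most abundant (16.3 CPM and above), 216 were called higher and 99 lower. Of 728 gene models with at least 100 CPM, 23 were higher and 10 lower. The 602 higher gene models took 1.47%, 2.19%, 2.61% and 2.12% of the counts in exercised replicates 1, 2, 4 and 5, and 1.06%, 0.96%, 1.02% and 0.98% in unexercised replicates 1, 2, 3 and 5. The 362 lower gene models took 0.38% to 0.53% of the counts in the same 4 exercised libraries and 0.76% to 0.85% in the same 4 unexercised libraries. Both sets were chosen on these libraries, so the shares describe them and are no separate test. In the left-out libraries the higher set took 2.22% in exercised replicate 3 and 1.8% in unexercised replicate 4. The lower set took 1.01% in exercised replicate 3, above each of the 8 libraries in the fit, and 1.22% in unexercised replicate 4.

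The number of calls with 8 libraries moved with the libraries in the fit. It was 1812 without exercised replicate 1, 358 without exercised replicate 2, 405 without exercised replicate 4, 529 without unexercised replicate 1, 574 without unexercised replicate 2, 403 without unexercised replicate 3 and 559 without unexercised replicate 5. Higher calls made up 62.4% of the calls with TMM factors, and in the same edgeR test 63.2% with RLE factors, 55% with upper-quartile factors and 55.9% with library totals only. In limma on log2 RPKM plus 1, which changes the test as well as the scaling, they made up 50.7% with RPKM recomputed from each library's own total (224 higher, 218 lower) and 87.0% with the deposited RPKM (248 higher, 37 lower).

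**Figure D3:**
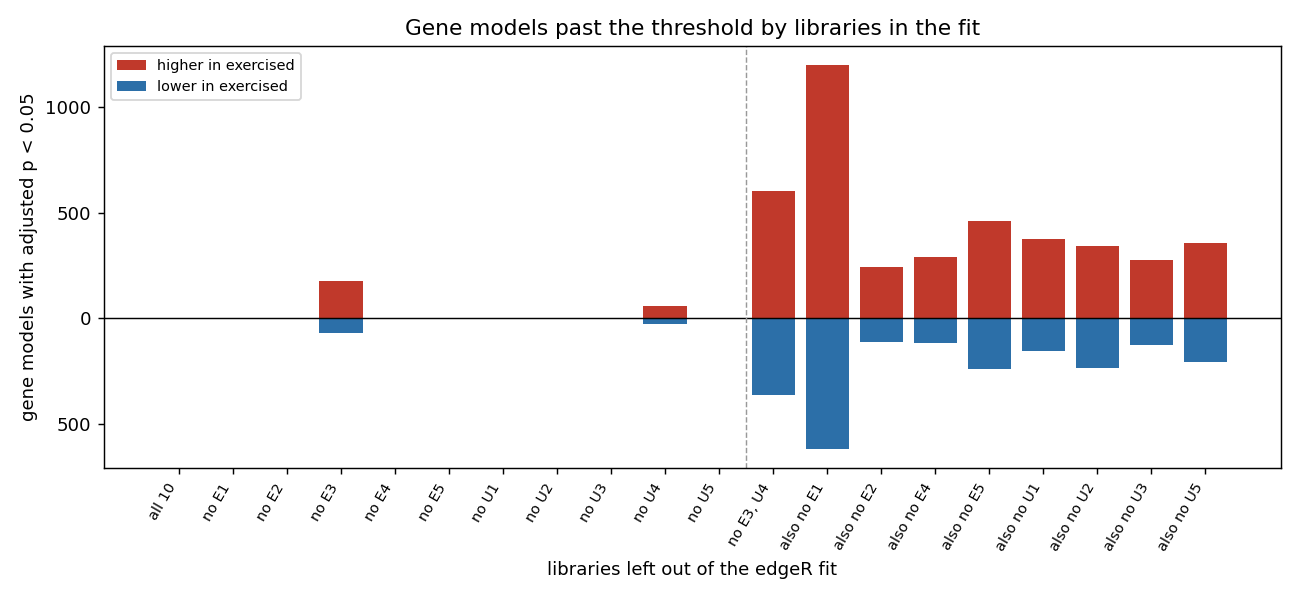
Gene models with an edgeR adjusted p under 0.05, higher (red, upward) and lower (blue, downward) in exercised muscle, by the libraries left out of the fit. Left of the dashed line, all 10 libraries (0 calls) and each library left out in turn; right of it, the 8 libraries without E3 and U4 (602 higher, 362 lower) and each of those left out in turn.

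The deposited RPKM values did not follow from each library's own total count. Gene lengths worked out from the counts, the RPKM and each library's own total varied between libraries by a median of 19% per gene model. With the 10 totals running down the rows of the table in place of across its columns, they varied by 0.0102%. In 13844 gene models with an RPKM of at least 1 in any library, 100% of the values matched the latter to within 0.1% plus 0.001. A library's own total was the divisor for 10% of the values. The ratio of a library's own total to that of another library ranged from 0.64 to 1.56.

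**Figure D4:**
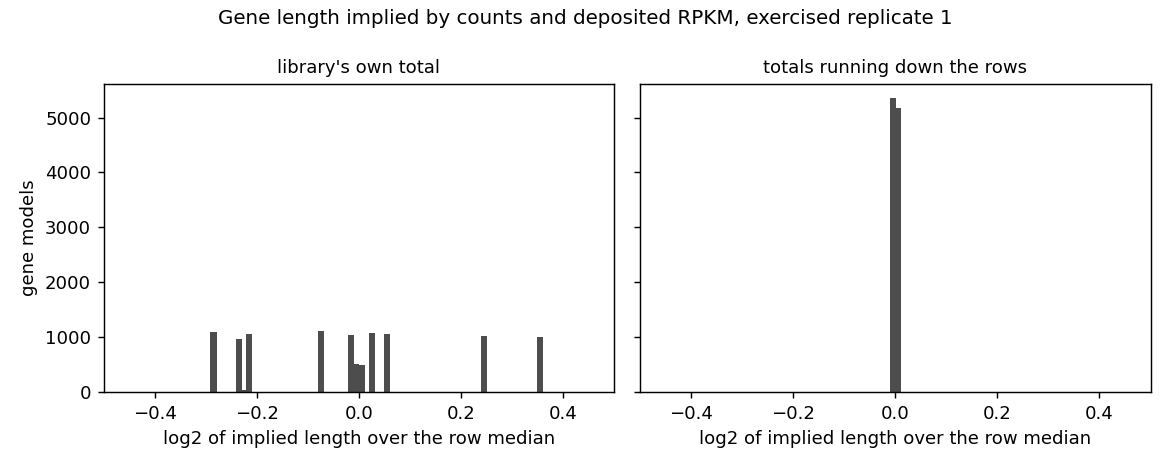
Number of gene models by the log2 ratio of the length implied in exercised replicate 1 to the median over libraries. With the library's own total (left) the lengths fall into separate groups, and with the totals running down the rows (right) they agree, with a median variation of 0.0102%.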

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

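The tests of gene length and of another tissue, the counts of other splits, the test of the left-out pair and the shuffling of called gene models were chosen after the results were seen; the test of a few dominant genes, that of a wider spread and that of split gene models were set before their results. All fits of 8 libraries were added after the data had been seen. The bar for the left-out pair was raised after its value was known, from exceeding every other split to exceeding them by more than its 95% interval; the value meets the earlier bar and not the later one.

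Exercised replicate 3 and unexercised replicate 4 lay far from the rest of their groups in 9 of 24 group-wise checks, where chance gives about 1.2. Their values were 25.78% and 24.19% for the share of the 10 most abundant gene models, 47.07% and 45.81% for the 100 most abundant, 1.678 and 1.697 for the TMM factor, and 126.1 and 133 for the first component. In exercised replicate 3, Nfu_g_1_019970 stood at 19.7 normalised CPM, against 10.5 to 12 in the rest of its group.

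The first pattern is a large set of gene models with higher levels in both of these libraries, 1 from each group. Its size depends on the scaling, 5884 and 5896 with library totals and 2458 and 2548 with TMM-scaled totals. With TMM-scaled totals the shift went both ways, as 1587 and 1669 gene models lay more than 2-fold below the median. The tests below cover the higher set, and sharing of the lower set was not tested. The values argue against gene length as the source, with a largest Spearman rho of 0.051 between length and deviation across genes. A few dominant genes taking the counts do not account for all of it. Without the 100 most abundant gene models and with totals rescaled, 3861 and 3815 of 15454 gene models still lay above 2-fold of the median. The other libraries had 91 to 411. These numbers are below the 5884 and 5896 of 13691 gene models with library totals, so dominant genes may account for a part. RNA of another tissue or cell type stays open as a source. Of the gene models high in exercised replicate 3, 88.6% were also high in unexercised replicate 4 (5211 gene models, against 2534 if independent; 88.3% with TMM-scaled totals). The 2 libraries were singled out because they stand apart together, so this sharing does not tell another tissue from any other source common to both. Without gene names no marker could be read. No biological explanation was tested, as the labels give these libraries nothing in common.

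The 0 calls with all 10 libraries and the 964 with 8 form the second pattern. With 10 libraries the count of splits decides nothing, since 100 of 100 splits must reach a real count of 0; the highest other split gave 115 calls, 1 of 38 that placed both libraries that stood apart in 1 group, and the other 37 of those gave 0 or 1. With 8 libraries, 1 of 35 splits, the real one, gave 964 calls and the highest other gave 5. At an unadjusted p under 0.05 the real split gave 3280 gene models and the highest other 2427. These counts argue against chance but do not exclude it, as ranking highest of 35 is the most the splits can show. The 8 libraries were also chosen after the data had been seen. Every other split mixes the groups, so the gap in calls does not measure the strength of the evidence. Standard errors of the called gene models were 1.36 times as large with 10 libraries. This lay between the bounds set against and for a wider spread as the reason. Their log2 fold changes were 0.84 times as large, which met the bound for it. These gene models were called with the 8 libraries, which favours small standard errors and large fold changes there. Both ratios may follow in part from that choice, and with the first undecided a wider spread stays open. The left-out pair differed in the called direction for 79.4% of the 964 (95% exact binomial interval 76.7% to 81.9%, too narrow as genes are not independent). The other splits gave at most 5 calls, so their shares are of their top gene models and not of calls. The median of these shares was 57%. They were 53.5% to 78.5% over the 16 splits that part the exercised libraries 3 and 1 and so keep part of the contrast. Over the 18 that part them 2 and 2 they were 50.2% to 63.5%. Such a split has no exercised side, so its direction is arbitrary and the comparison is a rough one. The interval does not lie above the highest of these shares, and the pair is 1 library against 1. A group difference shared by the pair therefore stays open, as does exercise itself as a hypothesis.

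The third pattern is that called gene models lay in neighbouring rows of the table, whose order is not explained in the sources used here. There were 77 neighbouring pairs called in 1 direction (65 higher, 12 lower), against a mean of 32.3 and a maximum of 53 in 10000 shuffles (p = 1e-04, permutation test, the smallest they can give), which argues against chance placing. Pairs in opposite directions numbered 26, against 28.8 shuffled. A gene split over 2 models, or reads shared by 2 models, may account for part of it. The median within-group correlation of a pair was 0.65, against 0.33 for random called pairs and 0.1 for any neighbours. Of the 77 pairs, 27 had an r of at least 0.8. The 50 left without them were still above the shuffled mean of 32.3, though under the maximum of 53. Pairs of high r were not taken out of the shuffles, so the 50 cannot say how much of the excess remains. The median of 0.65 lies between the bounds set against and for this explanation, so it stays open. Neighbouring genes regulated together were not tested.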

How the results depend on the processing

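With all 10 libraries the planned edgeR test called 0 gene models (1461 at an unadjusted p under 0.05), as it did with RLE or upper-quartile factors, no filter and the stricter filter. Library totals only gave 2 (2 higher), DESeq2 391 (266 higher, 125 lower; 9886 gene models got no adjusted p), voom with quality weights 1819 (1102 and 717), deposited RPKM plus 0.1 2 (2 higher), deposited RPKM plus 1 1 (1 higher) and 1 surrogate variable 836 (561 and 275). Added after seeing the data, recomputed RPKM plus 1 gave 2 (2 higher) and the 8 libraries 964 (602 and 362). Leaving out each library in turn gave 0 to 244 calls, 0 to 175 higher and 0 to 69 lower: 244 without exercised replicate 3, 84 without unexercised replicate 4 and 0 without any other. Of these calls, 355 of the 391, 934 of the 1819, 688 of the 836, 243 of the 244 and 84 of the 84 were among the 964 in the same direction. The voom weights were 0.122 for exercised replicate 3 and 0.116 for unexercised replicate 4, against 0.745 to 2.33 for the others. The cause of the differences between tests was not tested.

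With 8 libraries, library totals only gave 614 calls (343 higher, 271 lower), DESeq2 1540 (959 and 581), voom 1671 (1019 and 652), deposited RPKM plus 0.1 316 (272 and 44), deposited RPKM plus 1 285 (248 and 37), recomputed RPKM plus 1 442 (224 and 218) and 1 surrogate variable 1409 (847 and 562). RLE gave 959, upper-quartile factors 960, no filter 816 and the stricter filter 1025. Leaving out each library gave 358 to 1812 calls, 245 to 1196 higher and 113 to 616 lower; the highest was without exercised replicate 1 and the lowest without exercised replicate 2. The others were 405 without exercised replicate 4, 529, 574, 403 and 559 without unexercised replicates 1, 2, 3 and 5, and 703 without exercised replicate 5. Deposited RPKM plus 0.1 moved the median log2 fold change of all gene models to 0.15, from -0.01.

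On the first component the exact permutation p was 0.937 with the 500 most variable gene models, 0.778 with the deposited RPKM and 0.325 to 0.952 without each library; with a library that stood apart still in each of these, they say nothing about stability. It was 0.0286 with 8 libraries and 0.00794 on the second component. The 4 gene models given by identifier kept their direction in all 22 alternatives and passed the threshold in 6. Their log2 fold changes ranged from 1.97 to 2.4 (Nfu_g_1_000946), 0.81 to 1.87 (Nfu_g_1_004892), -2.17 to -1.52 (Nfu_g_1_007294) and -2.02 to -1.36 (Nfu_g_1_019970). With all 10 libraries the groups did not overlap for any of the 4, so the kept direction was nearly fixed in advance. The alternatives fixed for the gene lists and the transgene were not run, for lack of gene names. No paired analysis was run because the labels give no pairing. The title numbers of the groups do not overlap, which does not exclude a pairing.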

Other observations

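The tests here were chosen after the data had been seen. In the 10-library comparison, 62 of the 100 splits drawn placed exercised replicate 3 and unexercised replicate 4 in different groups. Among those 62, only the real split gave as many as 1461 gene models at an unadjusted p under 0.05, and no other gave more than 1 call. Over all 100 splits, 39 gave as many, the real one included, and the highest gave 3873.

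The fold differences of the gene models called with 8 libraries pointed the same way with 10 libraries for 960 of 964, and 712 of them had an unadjusted p under 0.05 there. The 8 libraries are part of the 10, so this is no separate test. In the left-out pair alone, exercised replicate 3 had the higher log2 CPM for 500 of the 602 gene models called higher, and unexercised replicate 4 for 265 of the 362 called lower. The median log2 difference of the pair was 0.34 for the first set, -0.24 for the second and 0.01 over all gene models tested. This compares 1 library with 1 and has no replicate check.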
